A study of Homo sapiens with 6 samples.

How the data were processed

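RNA from HK-2 cells, an established line of human proximal tubule epithelium, was sequenced 48 h after transfection with a plasmid for a PARP1 shRNA (shPARP1) or a control shRNA (shCtrl), with 3 libraries per group. Per the labels, polyadenylated RNA was selected, libraries were made with a stranded kit and sequenced in paired-end mode. The authors deposited a table of read counts per gene, whole numbers that were not normalized, and a table of FPKM values for the same 6 libraries, rounded to 2 decimals. Per the submitters' processing notes, the genome build was GRCh38 and the tools included bcl2fastq, TopHat2 and edgeR, without versions. The counting tool, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene overlapping it on the opposite strand may not have been separated. Reads of near-identical genes may likewise have been split or dropped in the deposited counts, which makes the values of multigene families uncertain.

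The deposited count table held 30403 genes. Library totals were 24429683, 26075322 and 26269194 counts in shCtrl replicates 1 to 3, and 32809303, 30502460 and 29387853 in shPARP1 replicates 1 to 3. At these totals, 3 counts correspond to between 0.0914 and 0.123 CPM. Within a group, the chi-square per degree of freedom between libraries lay above sampling noise for each pair, so that each library was counted as a separate replicate. The labels do not say whether the replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

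Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (16040 genes), library sizes were scaled with TMM, and groups were compared with the robust quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Values are given as TMM-scaled CPM, mean ± SD over 3 libraries, and log2 fold changes are shPARP1 against shCtrl. The design, the named-gene rule, 34 gene lists and most alternatives were fixed before the data were examined. The lists came from textbook knowledge and were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2, with an inter-gene correlation preset to 0.01, two-sided and adjusted over all lists. The test was repeated with an estimated correlation. Counts of called members are over all genes tested, and were also computed with p-values adjusted over the list alone.

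Genes were named by a rule. It took PARP1, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, a proper symbol and groups that did not overlap. It also took up to 4 called members of each list by smallest p-value, and genes including COL1A1, COL4A1, FN1 and CCN2 (CTGF in the deposited table). Some genes that the rule took are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

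Exon lengths, GC content, gene coordinates and 3′ UTR sequences came from GENCODE release 29 on GRCh38, to which 97.4% of the genes in the table were matched by Ensembl identifier. The exon length of a gene counted all its annotated exons merged. For the length and GC correction, each library's deviation from the gene mean was fitted with natural splines on log2 exon length and GC content, and the fit was entered as an offset. Of the tested genes, 99.2% had both values. Other alternatives were other scaling factors, other filters on low counts, edgeR's likelihood-ratio test, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a 2-fold minimum, the replicate number as a block, and leaving out each library. Counts thinned to the smallest library total, and camera after the length and GC correction, were added after seeing the data. Camera after that correction used the preset correlation. Bootstrap intervals and permutations were over genes or RNAs, all measured in the same 6 libraries. They do not measure the spread between replicates. Other computations used Python 3.11.15 with scipy 1.17.1.

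The gene test, the list test and the seed-site scan were tested on simulated data; the small-RNA and gene-family tests were not. With 200 of the 16040 genes changed in counts simulated from these libraries, the quasi-likelihood test recovered 48% of genes changed 1.25-fold, 68% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 10 false calls. With no list changed, camera called 0 of 34 lists, and with the ribosomal protein genes raised 1.25-fold it called 1, the raised list. Genes were simulated independently of each other, so these counts do not show how camera behaves when list members are correlated. In the real libraries the estimated correlation was 0.23 for ribosomal protein genes and 0.75 for mitochondrially encoded transcripts. For some other lists it lay below the preset, among them proteoglycan (-0.06) and epithelial junction genes (-0.03).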

Results

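The transcriptome of HK-2 cells, an immortalised line that keeps features of the human renal proximal tubule, was compared after knockdown of PARP1. PARP1 encodes the main nuclear poly(ADP-ribose) polymerase, which binds DNA breaks and chromatin. The title of the series names extracellular matrix genes, so these are described before the other gene groups. Polyadenylated RNA was sequenced from 3 shPARP1 and 3 shCtrl libraries 48 h after transfection. Library totals ranged from 24429683 to 26269194 counts in shCtrl and from 29387853 to 32809303 in shPARP1, so that all 3 knockdown libraries were deeper.

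PARP1 transcripts fell from 261 ± 2.37 CPM in shCtrl to 27.3 ± 1.37 CPM in shPARP1 (SD, n = 3 per group), a log2 fold change of -3.26 (SE 0.04, edgeR quasi-likelihood adjusted p = 1.7e-51). The knockdown libraries retained 10.4% ± 0.524 (SD, n = 3) of the control level. PARP1 (ENSG00000143799) lies on the minus strand of chromosome 1, from 226360691 to 226408079 on GRCh38, and its counts were 6275, 6827 and 6726 in shCtrl and 886, 807 and 858 in shPARP1.

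Of 16040 genes tested, 8937 (55.7%) changed, 4371 upward and 4566 downward. Most changes were small, with a median absolute log2 fold change of 0.49 among called genes, and 1039 genes changed at least 2-fold, 386 upward and 653 downward. Protein-coding genes made up 8211 of the called genes and other gene types 726. The CPM ranges of the groups did not overlap for 60.1% of the tested genes, against 10% by chance with 3 libraries against 3. The groups separated along the leading principal component, which held 64.2% of the variance, and the common biological coefficient of variation was 4.83%.

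Among called genes with a mean of at least 5 CPM and groups that did not overlap, the largest rise was that of CSF2, the gene for the cytokine GM-CSF (chromosome 5, 132073790 to 132076170), which went from 13.6 ± 1.33 CPM in shCtrl to 76.4 ± 3.72 CPM in shPARP1, a log2 fold change of 2.49 (SE 0.06). It was followed by MMP1 (2.18), an interstitial collagenase, the hair keratin-associated gene KRTAP2-3 (2.12), the telomerase RNA TERC (2.10) and GTF3A (2.02), a transcription factor for ribosomal RNA genes. Next came the intraflagellar transport gene IFT27 (1.97), the mitochondrial import receptor TOMM22 (1.95), the neutrophil chemokine CXCL3 (1.94), ASB2 (1.91) and the diacylglycerol kinase DGKG (1.87). KRTAP2-3 and CXCL3 have close paralogs, so their counts are uncertain. After PARP1, the deepest fall was in the ATPase gene OLA1 (-2.75), from 30.9 ± 2.11 CPM in shCtrl to 4.59 ± 0.447 CPM in shPARP1. The matrix gene MATN3 (-2.30), the lysosomal enzyme receptor IGF2R (-2.16), CLSTN2 (-2.14), PIK3IP1 (-2.08), the ephrin EFNB3 (-2.01), the desmosomal cadherin DSG2 (-1.98), the nucleolar methyltransferase fibrillarin FBL (-1.96) and the palmitoyltransferase ZDHHC20 (-1.96) followed. Values in parentheses are log2 fold changes here and in what follows.

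**Figure D1:**
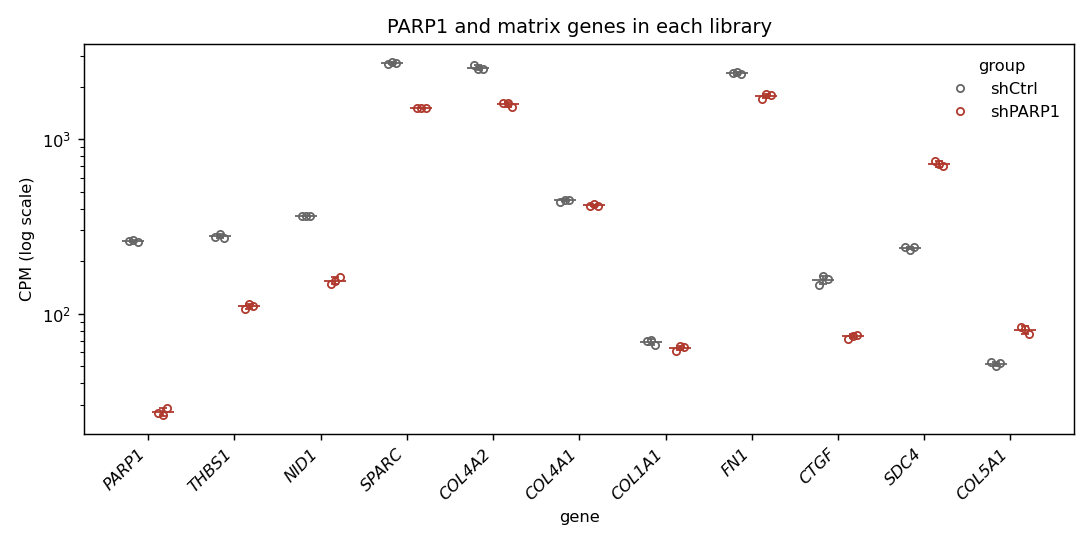
CPM on a log scale of PARP1 and matrix-related genes in each library (open circles), with the mean (bar) and SD (whisker) of 3 libraries per group. PARP1 fell from 261 to 27.3 CPM, THBS1, NID1, SPARC and COL4A2 lay lower in all shPARP1 libraries, COL1A1 and COL4A1 differed little, and SDC4 and COL5A1 lay higher.

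Genes of the extracellular matrix were mostly lower after PARP1 knockdown. Among extracellular matrix glycoproteins, 36 of 47 tested members fell, 3 rose and 8 did not pass the test. THBS1, a matricellular protein that activates latent TGF-beta, fell from 278 ± 7.51 CPM in shCtrl to 110 ± 3.58 CPM in shPARP1 (-1.34). NID1, a basement membrane linker, went from 363 ± 1.13 to 155 ± 7.69 CPM (-1.23), and SPARC, a collagen-binding protein, from 2744 ± 34.7 to 1515 ± 2.63 CPM (-0.86). MATN2 fell by 1.40 on the log2 scale. The list was called as a set (median log2 fold change -0.79, camera adjusted p = 2e-11, adjusted p = 0.0364 with an estimated correlation), with 38 lower members adjusted over the list alone. After correction for gene length and GC content its median was -0.67. Of 17 proteoglycan and hyaluronan synthesis genes, 13 fell and 1 rose, with 14 lower adjusted over the list alone. The heparan sulfate proteoglycans HSPG2 (-0.97), GPC4 (-0.86) and SDC3, which went from 545 ± 18.6 to 272 ± 5.26 CPM, fell, while SDC4 (syndecan-4), the member that rose, went from 238 ± 4.13 to 723 ± 26.5 CPM (1.61). This list too was called lower (median log2 fold change -0.75, camera adjusted p = 0.00055, adjusted p = 0.0851 with an estimated correlation).

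Collagen genes moved in both directions. Of 18 fibrillar and network collagens, 12 fell, among them COL4A2 (-0.70), COL8A1 (-0.81) and COL18A1 (-0.66), and 4 rose, among them COL5A1 (0.64). The basement membrane collagen gene COL4A2 went from 2572 ± 84.3 to 1582 ± 45.7 CPM. The fibrillar collagen gene COL1A1 changed little, from 68.6 ± 2.53 to 63.6 ± 1.97 CPM (-0.11, edgeR adjusted p = 0.0470), and so did COL4A1, from 446 ± 6.70 to 417 ± 4.97 CPM (-0.10, edgeR adjusted p = 0.00780). After correction for gene length and GC content the sign of both turned, to 0.08 for COL1A1 and 0.14 for COL4A1. Leaving out shCtrl replicate 2 gave -0.08 for each (edgeR adjusted p = 0.236 for COL1A1 and 0.0784 for COL4A1), and COL1A1 also lost its call without shCtrl replicate 1 (adjusted p = 0.124) and without shPARP1 replicate 1 (0.190), 2 (0.0678) or 3 (0.0607). The set test of the collagens lay near the threshold (median log2 fold change -0.20, camera adjusted p = 0.0459, adjusted p = 0.329 with an estimated correlation). It ended with the length and GC correction, where the median was -0.02 (adjusted p = 0.531), and without shCtrl replicate 2 (0.0525) or without shPARP1 replicate 1 (0.0521) or 3 (0.0648).

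Enzymes that modify and crosslink collagen were lower for 18 of 25 members and higher for 3 (median log2 fold change -0.22, camera adjusted p = 0.00055, adjusted p = 0.231 with an estimated correlation). The lysyl oxidases LOXL2 (-1.02), LOXL1 (-1.04) and LOX (-1.17) and the collagen galactosyltransferase COLGALT1 (-0.76) fell, LOXL2 from 3540 ± 85.3 to 1740 ± 17.3 CPM. Of 41 matrix proteases and inhibitors, 26 fell and 7 rose (median log2 fold change -0.47, camera adjusted p = 0.00133, adjusted p = 0.0851 with an estimated correlation). The metalloproteinase gene MMP15 (-1.33), ADAMTS12 (-1.22) and the inhibitor gene TIMP2 (-0.91) fell, in contrast to MMP1, and TIMP2 went from 669 ± 9.38 to 356 ± 4.85 CPM. Integrins and other matrix receptors fell for 16 of 26 members and rose for 4 (median log2 fold change -0.31, camera adjusted p = 0.00208, adjusted p = 0.195 with an estimated correlation), with falls of the focal adhesion gene VCL (-1.01), the integrin genes ITGB3 (-1.08) and ITGB5 (-0.64) and the collagen receptor DDR1 (-0.98). After correction for length and GC content the median of this list was -0.18 (adjusted p = 0.0281).

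TGF-beta pathway genes fell for 21 of 31 members and rose for 1, with 22 lower adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 4.4e-05, adjusted p = 0.0851 with an estimated correlation). The ligand TGFB2 (-1.12), the receptors TGFBR2 (-1.26) and ACVR1B (-0.63) and the target ID1 (-0.66) were among them, TGFB2 from 110 ± 4.96 to 50.6 ± 2.67 CPM. Target genes of the YAP and TAZ coactivators fell for 17 of 24 members and rose for 5 (median log2 fold change -0.47, camera adjusted p = 0.00111, adjusted p = 0.0851 with an estimated correlation). The connective tissue growth factor gene CTGF fell by 1.08 on the log2 scale (SE 0.04), and AXL (-0.75), CRIM1 (-1.43) and AMOTL2 (-0.97) fell as well. Epithelial junction genes fell for 23 of 31 members and rose for 1 (median log2 fold change -0.52, camera adjusted p = 5.5e-06, adjusted p = 0.0776 with an estimated correlation). They included DSG2, the tight junction gene CGNL1 (-1.14), the nectin gene PVRL1 (-0.73) and beta-catenin, CTNNB1 (-0.53). In the list on epithelial-mesenchymal transition, 11 of 22 members fell and 4 rose, and the set was not called (camera adjusted p = 0.0827). It was called without shPARP1 replicate 2 (camera adjusted p = 0.0494). The mesenchymal genes CDH2 (-0.75) and FN1 and the kidney cadherin CDH6 (-1.05) fell and the epithelial keratin KRT18 (0.59) rose, and fibronectin, FN1, went from 2388 ± 44.0 to 1767 ± 56.2 CPM (-0.43).

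**Figure D2:**
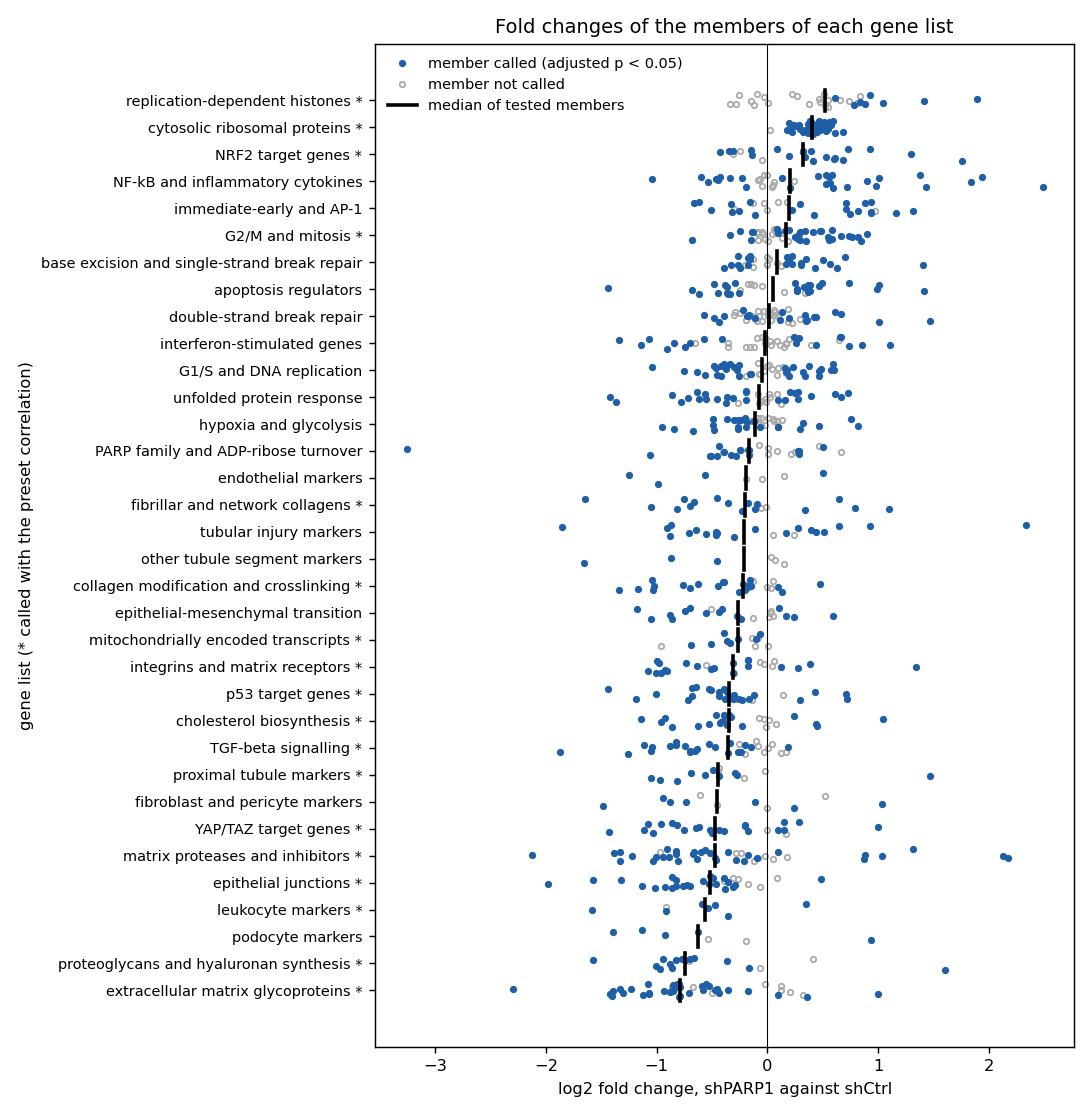
Log2 fold change, shPARP1 against shCtrl, of each tested member of the 34 gene lists (points, filled where called), with the median of each list (black bar), and an asterisk on the 18 lists called with the preset correlation. Extracellular matrix glycoproteins have the lowest median (-0.79), and 49 of 50 ribosomal protein genes lie above 0 as called genes.

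Genes of poly(ADP-ribose) turnover other than PARP1 changed less than the target. In the list of the PARP family and ADP-ribose turnover, 13 of 27 members, PARP1 included, fell and 4 rose, with 5 higher adjusted over the list alone, and the set was not called (camera adjusted p = 0.217). The tankyrase TNKS2 (-1.06), the NAD salvage enzyme NAMPT (-0.51) and PARP4 (-0.46) fell. Base excision and single-strand break repair genes rose for 15 of 33 members and fell for 9 (camera adjusted p = 0.244). The DNA glycosylases TDG (1.40) and NEIL2 (0.70) and the polymerase subunit POLD2 (0.35) rose, and the catalytic subunit POLD1 (-0.33) fell. For double-strand break repair, 12 of 44 members rose and 9 fell (camera adjusted p = 0.603), with falls of the DNA-dependent kinase PRKDC (-0.58) and FANCA (-0.44) and rises of the histone variant H2AFX (0.42) and the end-resection gene RBBP8 (1.01).

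Target genes of p53 fell for 22 of 29 members and rose for 4 (median log2 fold change -0.35, camera adjusted p = 0.00245, adjusted p = 0.163 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A (-0.44), GADD45B (-0.64), CCNG1 (-1.01) and CD82 (-0.39) fell, CDKN1A from 156 ± 5.99 to 115 ± 3.94 CPM. Genes of the G2/M phase and mitosis rose for 24 of 46 members and fell for 6 (median log2 fold change 0.16, camera adjusted p = 0.00410, adjusted p = 0.273 with an estimated correlation). The ubiquitin-conjugating enzyme of the anaphase-promoting complex, UBE2C (0.82), survivin BIRC5 (0.74), the mitotic kinase AURKB (0.58) and CKS2 (0.67) were among the rises. G1/S and replication genes were split between 14 rises and 18 falls among 44 (camera adjusted p = 0.628), with falls of the replicative helicase genes MCM6 (-1.05) and MCM5 (-0.46) and of TK1 (-0.49), and a rise of GINS2 (0.59).

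Several inflammatory cytokines rose. The chemokine gene CXCL8 went from 74.0 ± 4.16 CPM in shCtrl to 265 ± 7.91 CPM in shPARP1 (1.84), and CXCL2 (1.38) rose with CSF2, while CSF1 (-1.04) fell. Of 37 genes of the NF-kB and inflammatory cytokine list, 18 rose and 9 fell, but the set was not called (camera adjusted p = 0.0638). It was called without shCtrl replicate 1 (camera adjusted p = 0.0476) and without shPARP1 replicate 2 (0.0494) or 3 (0.0463). Immediate-early and AP-1 genes rose for 13 of 28 members and fell for 8, with 14 higher adjusted over the list alone (camera adjusted p = 0.113). The AP-1 subunit FOSL1 (0.89), the phosphatase DUSP5 (0.94) and PHLDA1 (0.82) rose, and MYC (-0.62) fell. Interferon-stimulated genes showed 9 rises and 9 falls among 39, with 7 higher adjusted over the list alone (camera adjusted p = 0.643). The signal transducer STAT2 (-0.91) and the effectors IFITM1 (-1.34) and IFI6 (-0.84) fell.

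Ribosomal protein genes rose together by a small amount. Of 50 members 49 rose and none fell (median log2 fold change 0.41, camera adjusted p = 2.8e-15, adjusted p = 0.163 with an estimated correlation), for example RPL11 (0.68), RPL24 (0.61), RPS20 (0.59) and RPL35 (0.54), RPL11 from 538 ± 19.2 to 863 ± 28.0 CPM. After correction for length and GC content the median was 0.34. Many of these genes have processed pseudogenes that can share reads. Targets of the oxidative stress factor NRF2 rose for 15 of 23 members and fell for 5 (median log2 fold change 0.32, camera adjusted p = 0.0344, adjusted p = 0.195 with an estimated correlation), with rises of thioredoxin TXN (0.73), the quinone reductase NQO1 (0.53), ferritin FTH1 (0.39) and PIR (1.29). This call ended with the stricter filter on low counts (adjusted p = 0.0574). Cholesterol synthesis genes fell for 16 of 25 members and rose for 4 (median log2 fold change -0.35, camera adjusted p = 0.0182, adjusted p = 0.233 with an estimated correlation). The regulator SREBF2 (-0.93) fell and PMVK (1.05) rose. Replication-dependent histone genes rose for 8 of 29 members and none fell (median log2 fold change 0.52, camera adjusted p = 0.0234, adjusted p = 0.329 with an estimated correlation), and HIST1H4C (1.89), HIST1H2BH (0.93), HIST1H4J (1.42) and HIST1H1C (0.61) had at most 5.89 CPM in a group mean. Their mRNAs lack a poly(A) tail and several are near-identical copies. Over all genes tested, 4371 of 16040 were called higher, a share near that of the histone genes. The histone call ended after the length and GC correction, where the median was 0.34 (adjusted p = 0.296), and without shPARP1 replicate 3 (adjusted p = 0.0527).

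Mitochondrially encoded transcripts fell for 8 of 13 members and none rose, with 9 lower adjusted over the list alone (median log2 fold change -0.27, camera adjusted p = 0.0157, adjusted p = 0.497 with an estimated correlation). The oxidase subunits MT-CO1 (-0.34) and MT-CO2 (-0.36) and the complex I subunits MT-ND1 (-0.27) and MT-ND4 (-0.51) fell. After correction for length and GC content the median was -0.56 (camera adjusted p = 2.5e-05 with the preset correlation). The corrected test was not repeated with an estimated correlation, which was 0.75 for this list before correction. The mitochondrial share of all counts was 12.7% ± 0.60 in shCtrl and 10.4% ± 0.43 in shPARP1 (SD, n = 3). Nuclear copies of mitochondrial sequence can share these reads. In the unfolded protein response, 16 of 36 members fell and 10 rose, with 18 lower adjusted over the list alone (camera adjusted p = 0.131). The lipoprotein receptor VLDLR (-1.43) and the disulfide isomerases PDIA3 (-0.62) and PDIA6 (-0.55) fell and the stress pseudokinase TRIB3 (0.67) rose. Hypoxia and glycolysis genes fell for 17 of 35 members and rose for 7 (camera adjusted p = 0.147), with falls of CA9 (-0.84) and the glucose transporters SLC2A1 (-0.49) and SLC2A3 (-0.96) and a rise of the phosphofructokinase gene PFKL (0.76). Apoptosis regulators showed 15 rises and 12 falls among 34, with 13 lower adjusted over the list alone (camera adjusted p = 0.578), and CYCS (0.99) and BID (0.46) rose.

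Markers of the proximal tubule fell for 9 of 14 tested members and rose for 1 (median log2 fold change -0.44, camera adjusted p = 0.00417, adjusted p = 0.135 with an estimated correlation). The transcription factor PAX8 (-0.28) and the brush-border peptidase DPP4 (-0.69) fell together with CDH6, which went from 446 ± 9.59 to 215 ± 5.18 CPM. Tubular injury markers were split between 8 rises and 12 falls among 22 (camera adjusted p = 0.258), and CD24, which can share reads with pseudogenes, went from 76.5 ± 4.04 to 21.1 ± 1.49 CPM (-1.86). IGFBP7 (-0.88) and SOX4 (-0.71) fell too. Markers of other cell types were also tested. Leukocyte markers fell for 6 of 8 members and rose for 1, with 7 lower adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 0.0339, adjusted p = 0.312 with an estimated correlation). The members with most reads were CD74 (-0.92), an invariant chain gene, CSF1R (-0.35) and ITGAX (-0.59), and CD14 (-1.58) fell as well. This call ended with the stricter filter on low counts (adjusted p = 0.0586). Markers of other tubule segments fell for 3 of 6 members (camera adjusted p = 0.294). These were SCNN1A (-0.87), AVPR2 (-1.66) and EGF (-0.46, edgeR adjusted p = 0.0425), which lost its call without shPARP1 replicate 2 (-0.30, adjusted p = 0.253) or 3 (0.0676) and without shCtrl replicate 1 (0.103) or 2 (0.125). Podocyte markers fell for 4 of 7 members and rose for 1 (camera adjusted p = 0.226), with a fall of SYNPO (-1.13) and a rise of NES (0.94). Fibroblast and pericyte markers fell for 5 of 11 and rose for 2 (camera adjusted p = 0.217), with falls of NOTCH3 (-0.74), LUM (-0.94) and PDGFRB (-1.49) and a rise of TAGLN (0.24). Endothelial markers fell for 3 of 7 and rose for 1 (camera adjusted p = 0.257), with falls of ENG (-0.99), EGFL7 (-0.57) and TIE1 (-1.25) and a rise of EHD3 (0.50).

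Together, 18 of the 34 lists were called, 4 upward and 14 downward, and of these calls that of the extracellular matrix glycoproteins held with an estimated correlation. For 24 lists the counts of called members were the same adjusted over the list alone.

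Fold changes followed gene length. Across 8544 protein-coding genes with a log2 CPM above 3, the log2 fold change and exon length had a Spearman rho of -0.28, where genes are not independent replicates. In 10 groups of increasing exon length, the median log2 fold change went from 0.35 in the shortest genes (median 1671 bases) to -0.17 in the longest (median 12844 bases). Core matrix genes, the collagens, glycoproteins and proteoglycans together, had a median exon length of 6529 bases, and the ribosomal protein genes 3505 bases.

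**Figure D3:**
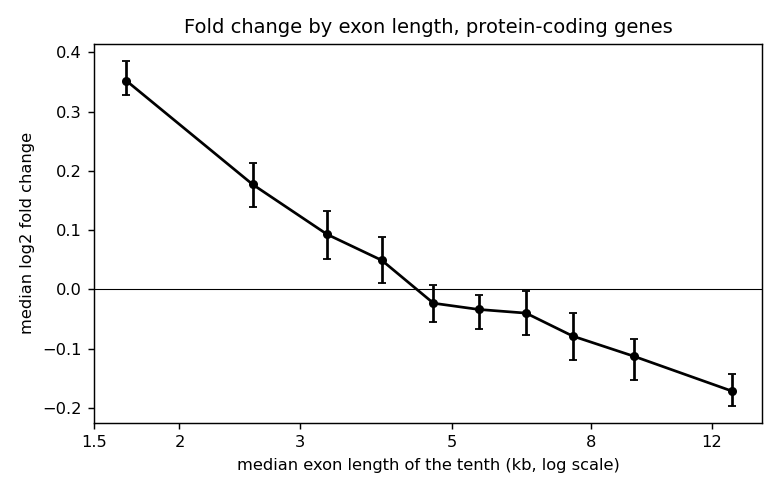
Median log2 fold change, shPARP1 against shCtrl, of 8544 protein-coding genes in 10 groups of increasing exon length (log axis, kb), with 95% bootstrap intervals over genes. The median goes from 0.35 in the shortest group to -0.17 in the longest.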

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

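Thinned counts and camera after the length and GC correction were chosen after seeing the data. The count of 8937 changed genes lay between 7005 and 9060 under the other tools, filters, scalings and corrections, and between 8220 and 8646 without each library in turn (4024 to 4349 higher, 4196 to 4416 lower). A 2-fold minimum left 1039 genes, 386 higher and 653 lower, a stricter threshold by construction. With FPKM values and a pseudocount of 1, 7395 genes were called, 4171 higher and 3224 lower, and 6999 of the main calls were kept. Thinning to equal depth gave 8759. The length and GC correction gave 9013 genes (4668 higher and 4345 lower) and kept 7806 of the calls, with 33 reversed. The PARP1 log2 fold change ranged from -3.01 to -3.30. COL1A1 turned to 0.0843 (edgeR adjusted p = 0.0860) with that correction and 0.0845 with the replicate block as well, and COL4A1 to 0.138 (edgeR adjusted p = 6.1e-06) and 0.139, which follows from the trend removed. Without the correction, the COL1A1 adjusted p reached 0.494 over its alternatives and that of COL4A1 0.327. Adding the replicate number as a block gave 9060 changed genes (4443 higher and 4617 lower) and 18 lists. Same-numbered libraries correlated by 0.0358, -0.00421 and 0.0362, and not every library correlated best with its own number, so the libraries were not treated as pairs. The correlation of deviations with GC content was 0.35, 0.01 and -0.37 in shCtrl replicates 1 to 3 and 0.50, -0.01 and -0.49 in shPARP1 replicates 1 to 3, the same order in both groups, and whether the numbers mark a shared step stays open. Against 18 lists, 1 was called with an estimated correlation, 16 with the stricter filter, 16 with the length and GC correction (17 with the block, where epithelial-mesenchymal transition was called, adjusted p = 0.0433) and 17 to 20 without each library. The rotation test fry, which does not compare a list with other genes, called 32 lists directionally and 34 in either direction. Of the smallest simulated changes, 48% were recovered, so small effects can be missed at this depth and replicate number.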

Other observations

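The families and RNA classes in this part, and the tests on seed sites and on box H/ACA RNAs, were chosen after the values had been seen. Nuclear genes for the mitochondrial ribosome rose for 76 of 78 tested members and none fell (median 0.57, camera adjusted p = 3.6e-20, adjusted p = 0.0104 with an estimated correlation). Proteasome subunits rose for 36 of 40 and none fell (median 0.59, camera adjusted p = 6.1e-13, adjusted p = 0.0104 with an estimated correlation), mitochondrial import genes, with TOMM22, rose for 19 of 23 and fell for 1 (median 0.49, camera adjusted p = 1e-06, adjusted p = 0.0151 with an estimated correlation), and complex I subunits rose for 32 of 38 and fell for 3 (median 0.46, camera adjusted p = 7.6e-09, adjusted p = 0.0287 with an estimated correlation), in contrast to the mitochondrially encoded subunits. RNA polymerase subunits rose for 20 of 30 and fell for 1 (median 0.37, camera adjusted p = 4.9e-06, adjusted p = 0.0307 with an estimated correlation). Solute carriers, membrane transporters, fell for 144 of 242 members and rose for 35 (median -0.34, camera adjusted p = 1.8e-07, adjusted p = 0.00897 with an estimated correlation). Semaphorins, plexins, ephrins and their receptors fell for 28 of 41 and rose for 3 (median -0.50, camera adjusted p = 4.9e-06, adjusted p = 0.0673 with an estimated correlation). Other families tested were called with the preset correlation but not with an estimated one. These were cytochrome oxidase subunits, with 11 of 13 higher (median 0.42, camera adjusted p = 0.00011, adjusted p = 0.144 with an estimated correlation), translation initiation factors, with 31 of 53 higher and 9 lower (median 0.29, camera adjusted p = 0.00044, adjusted p = 0.167 with an estimated correlation), zinc finger genes with ZNF symbols, with 108 of 441 higher and 46 lower (median 0.13, camera adjusted p = 0.0155, adjusted p = 0.0829 with an estimated correlation), protocadherins, with 7 of 16 lower (median -0.45, camera adjusted p = 0.0201, adjusted p = 0.167 with an estimated correlation), and myosins, with 8 of 20 lower and 2 higher (median -0.16, camera adjusted p = 0.0155, adjusted p = 0.167 with an estimated correlation). Of all 13292 protein-coding genes tested, 3931 were called higher and 4280 lower. The share of ZNF genes called higher was below that of all protein-coding genes. After the length and GC correction the medians were 0.43 for the mitochondrial ribosome, 0.49 for the proteasome, 0.28 for complex I, 0.19 for cytochrome oxidase, -0.03 for myosins and -0.27 for solute carriers.

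Small nucleolar and Cajal body RNAs of the box H/ACA class, which guide pseudouridylation, rose for 10 of 25 tested members and none fell, with a median log2 fold change of 0.80. TERC, the telomerase RNA that carries the same motif, went from 4.43 ± 0.523 to 19.0 ± 1.20 CPM (2.10; chromosome 3), and SNORA12 (2.59), SCARNA16 (2.33), SCARNA13 (1.61), SCARNA22 (1.43) and SNORA71B (1.36) rose. Apart from TERC these rises rest on few reads. Means in shCtrl were 0.34 CPM for SNORA12, 0.62 for SCARNA16, 1.13 for SCARNA13, 3.17 for SCARNA22 and 0.20 for SNORA71B. SNORA71B had 4, 4 and 7 counts in shCtrl and 18, 14 and 16 in shPARP1. Among box C/D RNAs, which guide ribose methylation, 2 of 21 rose and 1 fell. The rises were SNORD3B-1 (2.38) and SNORD3B-2 (2.36), near-identical copies, and the fall was SCARNA17 (-1.09). The related gene SNORD3A, with more reads (3.64 CPM in shCtrl and 3.61 in shPARP1), was not called (-0.01). All 6 tested genes for box H/ACA proteins rose, DKC1 (0.64), NHP2 (0.75), NOP10 (0.68), GAR1 (0.62), NAF1 (0.36) and SHQ1 (0.92), whereas the box C/D methyltransferase FBL fell (-1.96) and its partners NOP56 (0.30), NOP58 (0.42) and NHP2L1 (0.70) rose.

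The real grouping gave 8937 changed genes with edgeR's quasi-likelihood test, and the highest of the other 9 splits of the 6 libraries gave 0, with 123 to 171 genes at an unadjusted p under 0.05 and 0 genes by limma-voom. By chance 802 genes would reach that p, and a mixed split counts the difference between the groups as spread, so these splits call few genes by construction. For gene lists, the real grouping gave 18 and the other splits 5 to 12. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The split with 12 lists placed shCtrl replicates 1 and 2 with shPARP1 replicate 1.

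Core matrix genes were lower for 61 of 82 members, with a median log2 fold change of -0.68. A length trend as the whole cause is argued against. After removing a length and GC trend fitted on all other genes the median was -0.56 (95% bootstrap interval over genes -0.68 to -0.37). The collagens alone, however, went from -0.20 to -0.02 in the corrected fit. An off-target seed effect of the shRNA is a candidate explanation that was tested through the 7-base 3′ UTR site with the lowest z over 10096 genes, GAAATTA (z -6.16, against a lowest of -5.22 in 200 permutations), which occurs in the PARP1 transcript, as do 20.02% of all 7-base sites. Of 57 lower core matrix genes with enough reads and an annotated UTR, 7 held it (12.3%, exact 95% interval 5.08% to 23.7%). Among other genes 17.3% held it (Fisher's exact test, two-sided p = 0.382), which argues against this site as the main cause. Because the site was picked from these same fold changes, it need not belong to the shRNA. Over all genes searched, the mean log2 fold change left after a fit on UTR length, exon length and base content did not deepen with more sites (-0.0747 with 1, -0.0399 with 2, 0.0116 with 3 or more and 0.0129 with none). Other sites stay open because the shRNA sequence is not given in the sources used here, and so does an effect of PARP1 loss itself, which may lower matrix genes.

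Ribosomal protein genes rose for 49 of 50 members, with a median log2 fold change of 0.41. After removing the length and GC trend fitted on all other genes the median was 0.34 (95% bootstrap interval 0.29 to 0.44), which argues against that trend as the whole cause. A response of cells to PARP1 loss may contribute, and reads shared with pseudogenes were not tested.

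The higher box H/ACA RNAs could come in part from weaker poly(A) selection, for which the values point both ways. Their median exceeded that of 55 other RNAs without a poly(A) tail by 0.58 (95% bootstrap interval 0.16 to 1.08). Without the 29 histone genes among those others, the excess was 0.83 (interval 0.44 to 1.31, permutation p = 0.00029, two-sided). Intervals and permutations here are over RNAs, several of which share a host gene, and do not measure the spread between libraries. The medians were -0.13 for box C/D RNAs, 0.12 for 5 other small RNAs, of which RN7SL2 was called, and 0.52 for the histones. Reads of host genes stay open for the class, with a median difference from the host genes of 0.28 over 21 RNAs (interval 0.02 to 0.81), although SCARNA16, SCARNA22 and SNORA77 were called higher while their host genes were called lower, and TERC and SNORA11 rose without a tested host gene. The difference of 1.87 (interval 0.81 to 2.20) for the 8 called RNAs with a tested host decides nothing, because these were picked for their rise. The median of the 6 box H/ACA protein genes lay at percentile 99.4 of 10000 random lists matched on expression and length. Of 4 box C/D protein genes, 3 rose as well and FBL fell, while the median of box C/D RNAs was -0.13. The random lists drew genes independently, whereas these proteins share a complex. The percentile therefore cannot decide on the hypothesis that more of the protein complex may stabilise box H/ACA RNAs. No measurement of RNA stability or protein tests that link. Of 4 tested genes for 3′ end processing of small RNAs, PAPD5 rose (0.79), EXOSC10 fell (-0.27), and PARN and TOE1 were not called. What these changes do to the box H/ACA RNAs was not tested.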
